A study of Mus musculus with 24 samples.

How the data were processed

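RNA was sequenced from hind limb digit tips (bone, cartilage, marrow, dermis and epidermis together) of C57BL/6 mice, an inbred laboratory strain, after distal or proximal amputation. Per the labels, tissue was taken at 12, 14 or 21 days post amputation, total RNA was depleted of ribosomal RNA, and the 24 libraries form 6 groups of 4. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, part of which may be technical. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain.

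Per the submitters' processing notes, the tools were cutadapt, STAR 2.5.4b and featureCounts 1.6.3 of the Subread package, with genome build mm10. The deposited values for 15055 genes are whole numbers but were treated as a score, not as raw read counts. Their upper quartiles lay between 902.5 and 930.5 and their median-ratio factors between 0.966 and 1.04, while table totals, in units of 1e+06, ran from 15.3 to 19.4. Over the 9650 genes with every value above 100, the direction across libraries with the least spread had a natural-log spread of 0.00675, against 0.0453 from Poisson sampling alone, which is 6.71 times larger. Counted reads cannot lie that far below sampling noise. The values therefore look normalised and rounded, with a factor per library removed, a step that no label or header records. The direction with the next least spread lay slightly below sampling noise too, at 0.0428 against 0.0454. More than 1 factor may therefore have been removed. Group differences made up 0.194% of the direction with the least spread. The depth is unknown and no counting interval was computed. Nearly all of that direction lies within groups, where errors are estimated, so the p-values are likely too small. Every gene reached a value of at least 20 in some library.

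The design written before the data were examined assumed raw counts and named 2 count models; these were not run, because they need raw counts. Instead log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) over all 24 libraries with 6 group means, giving 18 residual and 3.91 prior degrees of freedom. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Errors of log2 changes are moderated standard errors. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 10 comparisons were distal against proximal amputation on each day, each pair of days within each level, and the difference between levels in the change from 12 to 21 days.

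Before the data were examined, 28 gene lists, the main comparisons, the alternatives and the rule for named genes were fixed. Lists with at least 3 measured members, 26 in all, were tested with camera at a preset correlation of 0.01; an estimated correlation and the rotation test fry were alternatives. Lists cover osteoblast and bone matrix, osteocyte, osteoclast, cartilage, tendon and ligament, fibrosis and myofibroblast, matrix proteases, nail matrix and hard keratin, epidermis, Wnt, BMP and hedgehog signalling, limb patterning and blastema, proliferation, hypoxia and glycolysis, stress and immediate early genes, macrophage, neutrophil, erythroid, adipocyte, skeletal muscle, endothelium, pericyte and smooth muscle, Schwann cell and nerve, sweat gland, mitochondrial transcripts, lymphocyte and melanocyte. The named genes are a panel of 10 (Bglap, Dmp1, Acp5, Acan, Tnmd, Postn, Krt85, Msx1, Lef1 and Mki67), the 6 largest rises and 6 largest falls between levels (4 and 4 for the other comparisons) among called genes with a mean log2 value of at least 1, per 1e+06 of the table total, and no overlap between groups, and up to 3 members of each list that was called or had at least 3 called members. Krt85 is not analysed here. Other members of the fixed lists are named where a passage goes through all measured members of a kind. Any other name was chosen after its values were seen, which is said where it occurs.

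Pseudocounts of 0.5 and 8, a filter at a mean value of 50 and the low-spread direction as a covariate were added after the data were seen. For counts and named genes, the alternatives fixed beforehand were median-ratio factors, table totals, a filter of 1 per 1e+06 in 4 libraries, limma-voom with sample quality weights, only the compared groups, the replicate number as a block, and each library left out in turn; no filter was applied, so the alternative without one is the main fit. For the list tests, those fixed beforehand were the 2 scalings, the block, the estimated correlation and fry. Simulated data were made from gene means and residual spreads over all 24 libraries, with changes put into the distal 12 day group. In 10 draws over 15055 genes, 200 of them changed, the fit recovered 83.6% of 2-fold and 97.9% of 4-fold changes. Of its calls, 5.24% were false. The noise was drawn independently for each gene and few genes were changed, so that share cannot be carried over to the calls in the data. Gene positions are from the GENCODE annotation of the mm10 assembly. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.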

Results

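In the adult mouse, the digit tip is known to regrow after a distal amputation and not after a proximal one. The series profiles bone and fibrous tissue formation by comparing transcripts after both amputations at 12, 14 and 21 days, with 4 libraries per group. Values below are the deposited normalised values (mean ± SD, n = 4); sequencing depth is unknown. Gm26917, named after its values were seen, was the highest gene in every library, with 3.39% to 7.96% of the table total. The first principal component held 25.05% of the variance, and 97.7% of it lay between groups. The second held 21.8%, and on it proximal 12 day replicate 1 lay at 24.96, with the other libraries of its group at 43.9 to 46.9.

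**Figure D1:**
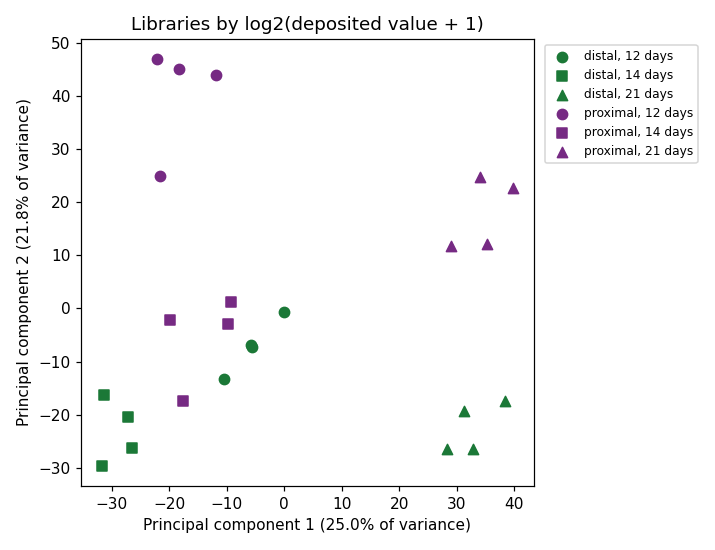
Each point is 1 library, placed by the first and second principal component of log2(deposited value + 1); colour gives the amputation level and shape the day. The 21 day libraries lie to the right, and proximal 12 day replicate 1 lies at 24.96 on the second component, below the rest of its group.

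At 12 days, the largest differences between levels, by the rule for named genes, were these. Krtap9-1, a keratin-associated protein gene (chromosome 11, 99873389 to 99874432), stood at 1865 ± 845 against 57.0 ± 55.3, a 42.9-fold difference (log2 5.42 ± 0.73, adjusted p = 2.13e-05). Gprc5d was 33.9-fold higher, Krt33a 26.3-fold, Krtap4-13 20.9-fold, Krtap16-3 20.7-fold and Krtap1-3 18.1-fold. C1qtnf3, a secreted C1q and TNF related protein gene (chromosome 15, 10952332 to 10980150), was 12.5-fold lower, at 194 ± 79.8 against 2250 ± 210 (log2 -3.64 ± 0.32, adjusted p = 1.31e-07). Mmp11, which encodes stromelysin-3, was 8.47-fold lower, Pamr1 8.08-fold, the noncoding transcript H19 6.33-fold, Cilp 6.21-fold and BC100530 6.02-fold.

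Of 16 measured nail matrix and hard keratin genes, 12 were higher and 0 lower, 13 adjusted over the list alone (adjusted p = 1.23e-11). The adjusted p = 0.0862 with an estimated correlation. Krt31 was higher by 3.15 ± 0.41 and Krt83 by 3.36 ± 0.47 on the log2 scale, as was Hoxc13, a transcription factor of hair and nail, by 1.56 ± 0.22. Keratin and keratin-associated genes share sequence, so reads may be split between them. The proliferation list was higher for 18 of 20 members, 20 adjusted over the list alone, with a median of 0.56 (adjusted p = 1.42e-11; adjusted p = 0.132 with an estimated correlation). Mki67, a marker of cycling cells, was at 6138 ± 814 against 3872 ± 457 (log2 0.66 ± 0.13), and Rrm2, a subunit of ribonucleotide reductase, was higher by 0.70 ± 0.13.

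The fibrosis and myofibroblast list was lower: 12 of 20 members were lower and 2 higher, 13 and 2 adjusted over the list alone (adjusted p = 2.65e-07; adjusted p = 0.0862 with an estimated correlation). Tgfb3 and Thbs2 both differed by -1.87 ± 0.15 and Loxl1, a lysyl oxidase like gene, by -1.42 ± 0.11. Tendon and ligament genes were lower for 9 of 16 members, 12 adjusted over the list alone (adjusted p = 4.96e-06; adjusted p = 0.129 with an estimated correlation), among them Ogn (-1.81 ± 0.26) and Col12a1 (-1.05 ± 0.16). Postn, the gene of periostin, was at 15020 ± 2910 against 47298 ± 7618 (log2 -1.66 ± 0.23). The cartilage list was not called (adjusted p = 0.0632), with 5 members lower and 1 higher, 6 and 1 adjusted over the list alone. Among them Acan (-1.65 ± 0.43) and Comp (-1.65 ± 0.28) were lower.

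The osteoclast list was higher (adjusted p = 0.0202; adjusted p = 0.694 with an estimated correlation), with 1 of 12 members called, Car2 (1.33 ± 0.29), and 1 adjusted over the list alone. That list call ended without distal replicate 4 (adjusted p = 0.0678), proximal replicate 2 (adjusted p = 0.2) or proximal replicate 3 (adjusted p = 0.0508). Bglap (1.66 ± 0.85), Dmp1 (1.43 ± 0.71), Acp5 (1.13 ± 0.48) and Msx1 (-0.30 ± 0.23) were not called. Single libraries weighed on the first 3 of these. In distal replicate 1, Bglap was at 20 (others 108 to 452) and Dmp1 at 26 (others 153 to 478). In proximal replicate 1, Acp5 was at 7558 (others 903 to 2252). Among signalling genes, the Wnt pathway transcription factor genes Lef1 (2.24 ± 0.44) and Tcf7 (1.72 ± 0.16), the BMP and activin inhibitor gene Bambi (1.62 ± 0.18) and Msx2 (2.05 ± 0.27) were higher, and Lgr5 (-1.38 ± 0.25) was lower. The Wnt (adjusted p = 0.831), BMP (0.117), limb patterning (0.374), protease (0.127), macrophage (0.272), osteoblast (0.113), osteocyte (0.831), epidermis (0.753) and hedgehog (0.374) lists were not called. Of Wnt members 2 were higher and 5 lower, 3 and 6 adjusted over the list alone; of proteases 3 and 7, 4 and 8 adjusted over the list alone. Tnmd (-1.24 ± 0.37) was lower, a call that ended without distal replicate 1 (-1.04) or proximal replicate 3 (-0.99), as did that of BC100530 without proximal replicate 4 (-2.02).

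In all, limma called 3053 of 15055 genes at 12 days, 1392 higher and 1661 lower after distal amputation, of which 284 and 241 by over 2-fold. With table totals as the scaling, the split was 845 and 1697, and with median-ratio factors 1605 and 1446. The values of the groups did not overlap for 3457 genes, 22.96%, where chance gives 2.86%.

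**Figure D2:**
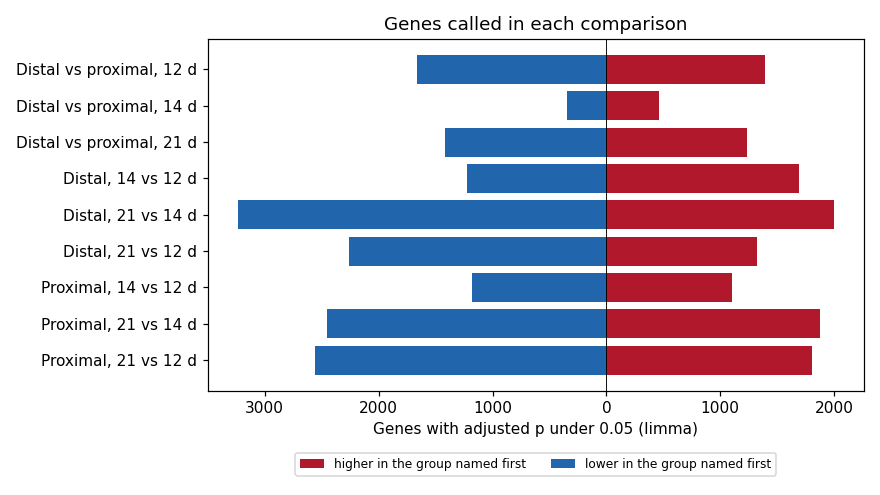
Bars give the number of genes called by limma in each of 9 comparisons, higher in the group named first to the right and lower to the left. Between levels, 3053, 811 and 2656 genes were called at 12, 14 and 21 days.

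At 14 days limb patterning genes were higher after distal amputation, and fewer genes were called than on the other days. Of 21 limb patterning and blastema genes, 8 were higher after distal amputation and 0 lower, 14 adjusted over the list alone, and 21 of 21 had a positive difference (median 0.52; adjusted p = 5.29e-10; adjusted p = 0.0637 with an estimated correlation). En1, a homeobox gene of the ventral limb, was at 1145 ± 248 against 413 ± 60.7 (log2 1.46 ± 0.20, adjusted p = 0.000775), and Prrx1 was higher by 0.52 ± 0.10. Wfdc18 (chromosome 11, 83709015 to 83711348) had the largest rise, 4.90-fold, at 3440 ± 735 against 710.5 ± 198 (adjusted p = 3.72e-05), and Pck1, the gluconeogenic carboxykinase (chromosome 2, 173153048 to 173159273), the largest fall, 6.81-fold, at 54.5 ± 22.04 against 448 ± 393 (adjusted p = 0.00965).

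The other large rises were Pappa2 (4.36-fold), Trpm2 (3.80-fold), Krt90 (3.19-fold), F5, coagulation factor V (3.09-fold), and Krt42 (3.01-fold). The other large falls were Tnfrsf13c, the BAFF receptor (4.41-fold), Atp12a (4.32-fold), H19 (2.97-fold), Trank1 (2.82-fold) and Aox4 (2.80-fold). The BMP list was higher, with 5 of 21 members called, 8 adjusted over the list alone (adjusted p = 0.000193; adjusted p = 0.0777 with an estimated correlation), among them Bmp4 (0.62 ± 0.13). The osteoblast and bone matrix list was higher, with a median of 0.72 and 17 of 17 positive, but 1 member called, Runx2 (1.02 ± 0.25), and 4 adjusted over the list alone (adjusted p = 4.13e-05; adjusted p = 0.623 with an estimated correlation). The hedgehog list was higher (adjusted p = 0.0255; adjusted p = 0.0827 with an estimated correlation), with 1 of 9 called, the receptor gene Ptch1 (0.73 ± 0.14), and 2 adjusted over the list alone. The epidermis list was lower (median -0.48; adjusted p = 0.00125; adjusted p = 0.410 with an estimated correlation), with 1 of 18 called, Krt2 (-1.56 ± 0.41), and 4 adjusted over the list alone.

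The osteoclast and proliferation lists were higher and the stress list was lower (adjusted p = 0.0415 for each; adjusted p = 0.976, 0.976 and 0.861 with an estimated correlation), each with 0 members called in limma and 0 adjusted over the list alone. Medians were 0.72, 0.19 and -0.24, and each of these list calls ended when 1 library was left out, with the highest adjusted p = 0.215 (without proximal replicate 2), 0.336 (without distal replicate 2) and 0.579 (without proximal replicate 1). The nail list was not called (adjusted p = 0.959, median 0.14). Of the panel, none was called: Acan (0.15 ± 0.43), Acp5 (0.91 ± 0.48), Bglap (0.42 ± 0.85), Dmp1 (0.17 ± 0.71), Lef1 (0.75 ± 0.44), Mki67 (-0.01 ± 0.13), Msx1 (0.40 ± 0.23), Postn (0.03 ± 0.23) and Tnmd (-0.57 ± 0.37). limma called 811 genes, 461 higher and 350 lower (68 and 37 by over 2-fold), and 1698 genes did not overlap, 11.3% against 2.86% by chance. The count was 450 with table totals and 261 in a fit of these groups alone. It was 277 without distal replicate 2 and 302 without distal replicate 3. Without proximal replicate 1, 2 or 3 it was 380, 397 or 322. Calls ended when 1 library was left out for Aox4 (distal replicate 1, 2, 3 or 4 or proximal replicate 1, -0.91 to -1.64), Atp12a (distal 3 or 4 or proximal 1, 2 or 3, -1.73 to -2.235) and Krt42 (distal 2, 3 or 4 or proximal 1, 2 or 3, 1.42 to 1.68). The same held for Pappa2 (distal 3 or proximal 1 or 2, 1.75 to 2.13), Trpm2 (distal 2 or 4 or proximal 2 or 3, 1.52 to 1.80), Runx2 (distal 2 or 3 or proximal 1, 2 or 3, 0.90 to 1.035) and Krt2 (distal 1, 2 or 3 or proximal 1 or 3, -1.28 to -1.52).

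**Figure D3:**
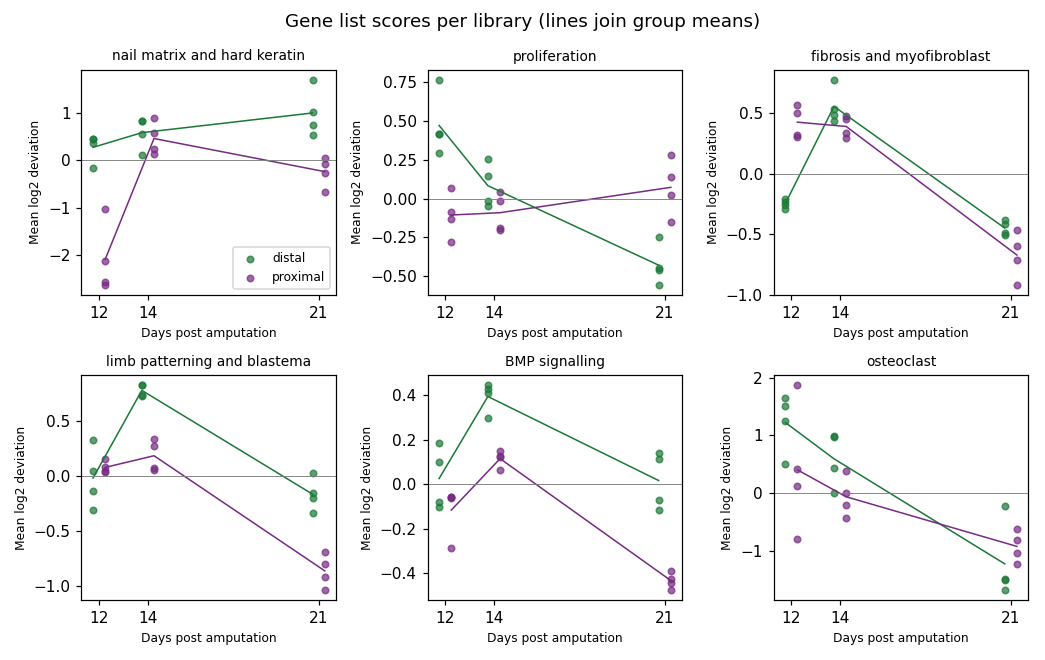
Points are libraries, coloured by amputation level, and lines join group means; the y axis is the mean log2 deviation of a list's members from their mean over all libraries, the x axis the day. The proliferation list lies higher after distal amputation at 12 days and lower at 21 days.

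At 21 days, the limb patterning and BMP lists were higher after distal amputation. Mtcl1 (chromosome 17, 66336982 to 66449750) was at 1140 ± 37.3 against 114 ± 17.1, 9.97-fold higher (log2 3.32 ± 0.21, adjusted p = 3.69e-09). Golga7b was 21.7-fold higher, Cybrd1, a ferric reductase gene, 14.8-fold, Krtap16-3 11.1-fold, Creg2 10.2-fold and Krt33a 9.71-fold. Mmp12, macrophage elastase, was 15.4-fold lower at 6.25 ± 5.91 against 142 ± 151, Klk6 14.3-fold, Sprr2d 7.28-fold, Atp12a 6.31-fold, Matn4 5.42-fold and Sgpp2 4.46-fold. Sprr2d was not called with sample quality weights (log2 -2.68).

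Of 21 limb patterning genes 14 were higher and 0 lower, 14 and 1 adjusted over the list alone (adjusted p = 2.39e-09; adjusted p = 0.0414 with an estimated correlation), with Msx2 at 982 ± 285 against 191 ± 42.9 (log2 2.34 ± 0.27) and En1 higher by 1.95 ± 0.20. Of 21 BMP genes 12 were higher and 2 lower, 13 and 2 adjusted over the list alone (adjusted p = 1.19e-07; adjusted p = 0.0149 with an estimated correlation), with Bambi (2.15 ± 0.18) and Smad6 (1.19 ± 0.10) among the higher. The nail list had 12 higher and 1 lower of 16, the same counts adjusted over the list alone (adjusted p = 5.92e-06; adjusted p = 0.268 with an estimated correlation), and the lower gene was Tchh, trichohyalin (-1.91 ± 0.45), not called in a fit of these groups alone. The Wnt list had 6 of 19 higher, 7 adjusted over the list alone (adjusted p = 4.99e-05; adjusted p = 0.113 with an estimated correlation), with Tcf7 (1.32 ± 0.16) and Nkd1 (1.34 ± 0.17). Lef1 was at 216 ± 60.8 against 47.5 ± 7.14 (log2 2.13 ± 0.44).

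The proliferation list had 14 of 20 lower, 18 adjusted over the list alone, and 0 of 20 positive (adjusted p = 7.14e-08; adjusted p = 0.268 with an estimated correlation). Mki67 was at 3856 ± 621 against 5584 ± 1026 (log2 -0.53 ± 0.13), and Cdk1 differed by -0.59 ± 0.13. The hypoxia and glycolysis list was higher for 5 of 14, 6 adjusted over the list alone (adjusted p = 0.000112; adjusted p = 0.287 with an estimated correlation), as Bnip3 (0.98 ± 0.18). The cartilage list was higher for 6 of 15, the same count adjusted over the list alone (adjusted p = 0.00702; adjusted p = 0.492 with an estimated correlation). Col10a1, the collagen of hypertrophic cartilage (chromosome 10, 34389981 to 34397085), was at 3972 ± 2056 against 567 ± 540 (log2 3.13 ± 0.65). The cartilage call ended without proximal replicate 2 (adjusted p = 0.1). The fibrosis list was higher with 3 up and 1 down of 20, the same counts adjusted over the list alone (adjusted p = 0.0273; adjusted p = 0.485 with an estimated correlation), and this ended without distal replicate 1 (adjusted p = 0.0598) or proximal replicate 3 (adjusted p = 0.1921). Lrrc15, its largest member, was higher by 1.88 ± 0.34.

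The erythroid list was called at 21 days (adjusted p = 0.00192; adjusted p = 0.485 with an estimated correlation) with 2 of 6 members higher, 5 adjusted over the list alone. The 2 were the near-identical globin genes Hba-a1 (869 ± 768 against 87.2 ± 126) and Hba-a2 (600.25 ± 534 against 56.0 ± 85.0), whose calls ended when distal replicate 1, 3 or 4 or proximal replicate 2, 3 or 4 was left out (3.19 to 3.97 for Hba-a1). The protease list was not called (adjusted p = 0.878, median 0.01, mean -0.45), with 2 higher and 5 lower, 3 and 6 adjusted over the list alone; Mmp13 differed by -1.75 ± 0.44. Of the panel, Msx1 was higher by 0.85 ± 0.23, a call that ended without proximal replicate 2 (0.70). Acan (0.96 ± 0.43), Acp5 (-0.21 ± 0.48), Bglap (-0.94 ± 0.85), Dmp1 (0.02 ± 0.71), Postn (-0.25 ± 0.23) and Tnmd (-0.38 ± 0.37) were not called. limma called 2656 genes, 1237 higher and 1419 lower (261 and 206 by over 2-fold), and 2833 did not overlap, 18.8% against 2.86% by chance. Table totals gave 4186 genes, 627 higher and 3559 lower, with the median of all genes at -0.19; median-ratio factors gave 1579 and 1031.

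Between the days, 211 genes were higher after distal amputation at both 14 and 21 days, against 37.9 for independent lists, and 330 at both 12 and 21 days, against 114 (Fisher's exact test, adjusted p = 5.49e-108 and 1.04e-78). At 12 and 14 days the count was 91 against 42.6 (adjusted p = 3.66e-12). For genes lower on both days the counts were 100 against 33.0 (14 and 21 days), 238 against 157 (12 and 21) and 78 against 38.6 (12 and 14) (adjusted p = 1.05e-24, 1.09e-11 and 1.66e-09). Of genes with opposite directions, 178 were higher at 12 and lower at 21 days, against 131 (adjusted p = 1.78e-05), and 142 lower and then higher, against 136 (adjusted p = 0.602). In the same order, the counts for 12 and 14 days were 29 against 32.4 and 47 against 50.9 (adjusted p = 0.602 for each), and for 14 and 21 days 6 against 43.5 and 4 against 28.8 (adjusted p = 5.23e-13 and 7.06e-09). These comparisons share no libraries, but they share each gene's error from the same fit, and genes are not independent. A gene with a small error is more easily called on every day. The counts for independent lists may therefore be too low and these p-values too small. 135 genes were called on all 3 days, 62 higher and 40 lower each time. The count was 51 in fits of the compared groups alone and 94 with table totals. It was 59 or 65 without distal 14 day replicate 2 or 3, and 70, 69 or 78 without proximal 14 day replicate 1, 2 or 3.

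The change from 12 to 21 days differed between levels for 2234 genes, 1117 in each direction. Table totals gave 595 and 1374, with the median of all genes at -0.10, and median-ratio factors 1227 and 1024. All 20 proliferation genes differed in the same direction, 20 adjusted over the list alone (median -1.11; adjusted p = 9.66e-18; adjusted p = 0.0644 with an estimated correlation), with Mki67 at -1.19 ± 0.19. Fibrosis genes differed the other way, 12 of 20 and 12 adjusted over the list alone (median 1.08; adjusted p = 2.73e-09; adjusted p = 0.0635 with an estimated correlation), as did limb patterning genes, 11 of 21 and 13 adjusted over the list alone (adjusted p = 1.89e-07; adjusted p = 0.0763 with an estimated correlation). Postn differed by 1.42 ± 0.33 and Acan by 2.61 ± 0.60. The largest differences were S100a9 (-6.28 ± 1.70), S100a8 (-5.13 ± 1.35), Krtap26-1 (-4.27 ± 0.92), Mmp3 (-4.17 ± 0.81), Col10a1 (4.53 ± 0.92), Crnn (3.48 ± 1.00), Cyp26a1 (3.10 ± 0.59) and Col9a2 (2.96 ± 0.72). S100a9 was not called with quality weights, and Crnn not without proximal 21 day replicate 3 (2.96). The cartilage list (median 1.51, 8 called and 8 adjusted over the list alone), the tendon list (1.08, 4 and 5) and the Wnt list (0.38, 7 and 9) also differed upward, with adjusted p = 0.000317, 4.24e-05 and 0.00544, and adjusted p = 0.267, 0.136 and 0.208 with an estimated correlation. The BMP list did so with 4 members higher and 1 lower, 5 and 1 adjusted over the list alone (adjusted p = 0.0067; adjusted p = 0.165 with an estimated correlation). The nail list (median -1.44, 1 called and 0 adjusted over the list alone) and the osteoclast list (-0.83, 0 and 0) differed downward, with adjusted p = 0.0067 and 0.0166, and adjusted p = 0.498 and 0.657 with an estimated correlation; the osteoclast call ended without proximal 12 day replicate 2 (adjusted p = 0.101). Msx1 differed by 1.15 ± 0.33, a call that ended without distal 12 day replicate 1 (0.97), proximal 12 day replicate 3 (1.03) or proximal 21 day replicate 2 (1.00). The neutrophil list had a median of -4.22, with 3 members called and 4 adjusted over the list alone (adjusted p = 0.0067, and adjusted p = 0.136 with an estimated correlation). Only 4 of its 13 members were measured: S100a8, S100a9, Csf3r and Cxcr2. Whether the difference reflects neutrophils therefore stays open.

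**Figure D4:**
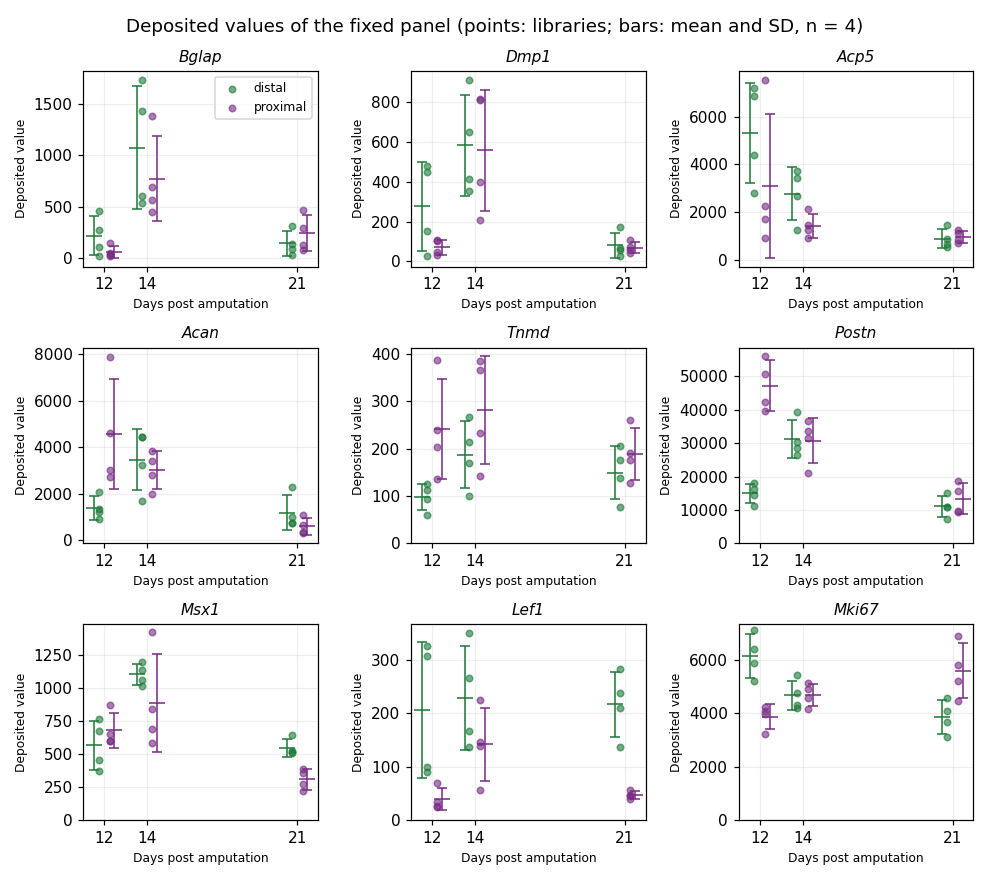
Points are the 4 libraries of each group, bars the mean and SD, and the y axis the deposited value of each of the 9 measured panel genes; the x axis is days post amputation. Postn lies higher after proximal amputation at 12 days, 47298 against 15020.

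From 12 to 14 days after distal amputation, fibrosis genes rose for 17 of 20, the same count adjusted over the list alone (adjusted p = 5.36e-11; adjusted p = 0.0223 with an estimated correlation), and limb patterning genes for 16 of 21, 17 adjusted over the list alone (adjusted p = 2.73e-10; adjusted p = 0.0223 with an estimated correlation). Hedgehog genes rose for 5 of 9, the same count adjusted over the list alone (adjusted p = 0.00201; adjusted p = 0.0223 with an estimated correlation). Msx1 rose from 568 ± 185 to 1102 ± 77.7 and Postn from 15020 ± 2910 to 31227 ± 5639. Osteoblast genes rose for 8 of 17, 10 adjusted over the list alone (adjusted p = 2.38e-05; adjusted p = 0.244 with an estimated correlation), and Bglap, osteocalcin, from 212 ± 190 to 1075 ± 604, a call that ended without distal 12 day replicate 1 (1.99) or distal 14 day replicate 1 (2.57) or 2 (2.67). Proliferation genes fell for 7 of 20, 14 adjusted over the list alone (adjusted p = 1.44e-06; adjusted p = 0.235 with an estimated correlation). Frzb (2.46 ± 0.44), Fam180a and Col9a2 (both 2.26) led the rises with Bglap; Cyp4a29 (-3.10 ± 0.47), Il11 (-2.54 ± 0.36), Alox12e (-2.41 ± 0.80; call ended without distal 12 day replicate 1, 2 or 4 or distal 14 day replicate 1, 2 or 3, -1.94 to -2.49) and Serpinb6c (-2.30 ± 0.43) led the falls. Of 26 lists tested, 13 were called and 3 with an estimated correlation. Those not given above had at most adjusted p = 0.0235, and at least adjusted p = 0.122 with an estimated correlation. Brackets give members called and then those adjusted over the list alone. Higher were osteocyte (3 and 5 of 7), cartilage (6 and 7 of 15), tendon (5 and 5 of 16), Wnt (6 and 6 of 19), BMP (6 and 6 of 21) and endothelium (0 and 0 of 11). Lower were epidermis (8 and 8 of 18) and stress (3 and 3 of 14). limma called 2915 genes, 1693 higher and 1222 lower.

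From 14 to 21 days after distal amputation, fibrosis genes fell for 16 of 20 and rose for 1, the same counts adjusted over the list alone (adjusted p = 5.41e-08; adjusted p = 0.0570 with an estimated correlation), and limb patterning genes fell for 15 of 21 and 16 adjusted over the list alone (adjusted p = 5.11e-07; adjusted p = 0.0930 with an estimated correlation). Osteoblast genes fell for 13 of 17 and rose for 1, the same counts adjusted over the list alone (adjusted p = 2.01e-05; adjusted p = 0.272 with an estimated correlation), and endothelial genes for 11 of 11 and 11 adjusted over the list alone (adjusted p = 2.61e-06; adjusted p = 0.195 with an estimated correlation). Ibsp, bone sialoprotein, fell from 14743 ± 5956 to 922 ± 338, Dmp1 from 583 ± 254 to 80.8 ± 62.6 and Acp5 from 2766 ± 1103 to 873 ± 406. Col10a1 rose from 101 ± 33.9 to 3972 ± 2056 (log2 5.19 ± 0.65). Stress and immediate early genes rose for 12 of 14, 13 adjusted over the list alone (adjusted p = 5.29e-09; adjusted p = 0.0570 with an estimated correlation), with Fosb among the largest (2.62 ± 0.34). Of 26 lists tested, 12 were called and 0 with an estimated correlation. Those not given above had at most adjusted p = 0.00544, and at least adjusted p = 0.1 with an estimated correlation. Higher were epidermis (7 and 7 of 18). Lower were osteoclast (11 and 11 of 12), tendon (7 and 7 of 16), protease (14 and 14 of 19), proliferation (12 and 15 of 20), macrophage (9 and 11 of 13) and pericyte (7 and 7 of 10). limma called 5234 genes, 1996 higher and 3238 lower; median-ratio factors gave 2742 and 2758, table totals 1365 and 3258.

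Over the whole interval from 12 to 21 days after distal amputation, proliferation genes fell for 19 of 20, 20 adjusted over the list alone (adjusted p = 1.09e-14; adjusted p = 0.225 with an estimated correlation), and osteoclast genes for 11 of 12, 11 adjusted over the list alone (median -2.78; adjusted p = 3.49e-07; adjusted p = 0.271 with an estimated correlation). Acp5, the tartrate-resistant phosphatase of osteoclasts, fell from 5307 ± 2096 to 873 ± 406, and Mmp3 (-4.59 ± 0.57), Mmp13 (-4.12 ± 0.44), Dcstamp (-4.12 ± 0.67) and Il1rl1 (-3.93 ± 0.52) fell most. Macrophage genes fell for 6 of 13, 7 adjusted over the list alone (adjusted p = 0.000261; adjusted p = 0.271 with an estimated correlation). Of 26 lists tested, 8 were called and 0 with an estimated correlation. Those not given above had at most adjusted p = 0.0238, and at least adjusted p = 0.225 with an estimated correlation. Higher were nail (1 and 1 of 16) and stress (6 and 8 of 14). Lower were protease (6 and 9 of 19, 0 and 1 higher), neutrophil (3 and 4 of 4) and endothelium (6 and 10 of 11). limma called 3584 genes, 1326 higher and 2258 lower; median-ratio factors gave 1831 and 1937, table totals 675 and 2607.

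After proximal amputation, nail genes rose from 12 to 14 days for 14 of 16, 14 adjusted over the list alone (median 3.40; adjusted p = 2.89e-15; adjusted p = 0.0462 with an estimated correlation). Gprc5d rose by 4.29 ± 0.64, Krt35 by 4.13 ± 0.71 and Krt33a by 4.07 ± 0.71, and Bglap from 56.0 ± 56.5 to 774 ± 419. Endothelial genes rose for 6 of 11, 7 adjusted over the list alone (adjusted p = 7.5e-05; adjusted p = 0.648 with an estimated correlation). Wfdc17 (-2.47 ± 0.42) and Cyp4a29 (-2.49 ± 0.47) fell. Of 26 lists tested, 4 were called and 1 with an estimated correlation. Those not given above had at most adjusted p = 0.0475, and at least adjusted p = 0.558 with an estimated correlation. Higher were osteoblast (3 and 3 of 17) and BMP (5 and 5 of 21). limma called 2288 genes, 1107 higher and 1181 lower; table totals gave 613 and 1586, median-ratio factors 1211 and 1072. Without proximal 12 day replicate 1 the count was 1649.

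From 14 to 21 days after proximal amputation, fibrosis genes fell for 16 of 20, 17 adjusted over the list alone (adjusted p = 1.04e-11; adjusted p = 0.0192 with an estimated correlation), and limb patterning genes for 18 of 21, 18 adjusted over the list alone (adjusted p = 1.27e-11; adjusted p = 0.0192 with an estimated correlation). Msx1 fell from 884 ± 371 to 308 ± 76.3 and H19 from 1095 ± 366 to 194 ± 88.9. Far2 (4.07 ± 0.76), Serpina3b (4.67 ± 1.07) and Klk6 (3.77 ± 0.85) rose. Of 26 lists tested, 16 were called and 2 with an estimated correlation. Those not given above had at most adjusted p = 0.0347, and at least adjusted p = 0.0574 with an estimated correlation. Higher were epidermis (3 and 2 of 18), proliferation (0 and 0 of 20) and stress (9 and 11 of 14). Lower were osteoblast (11 and 13 of 17), osteoclast (4 and 4 of 12), cartilage (8 and 8 of 15, 1 and 1 higher), tendon (6 and 6 of 16), protease (9 and 10 of 19, 0 and 1 higher), Wnt (8 and 10 of 19, 1 and 1 higher), BMP (11 and 12 of 21), hypoxia (5 and 5 of 14), macrophage (5 and 7 of 13), endothelium (10 and 10 of 11) and pericyte (6 and 7 of 10). limma called 4328 genes, 1876 higher and 2452 lower; table totals gave 3015 and 1563, with the median of all genes at 0.11, and median-ratio factors 2020 and 2372. After both amputations, 1683 genes were lower at 21 than at 14 days, against 527 for independent lists, and 836 were higher, against 249. Here too the comparisons share each gene's error.

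From 12 to 21 days after proximal amputation, fibrosis genes fell for 15 of 20 and rose for 2, 16 and 2 adjusted over the list alone (adjusted p = 5.9e-10; adjusted p = 0.0421 with an estimated correlation), while nail genes rose for 13 of 16, 14 adjusted over the list alone (adjusted p = 1.04e-07; adjusted p = 0.114 with an estimated correlation). Postn fell from 47298 ± 7618 to 13409 ± 4564, Acan from 4564 ± 2371 to 616 ± 366 and Capn6 by 3.07 on the log2 scale, and Mki67 rose from 3872 ± 457 to 5584 ± 1026. Of 26 lists tested, 13 were called and 1 with an estimated correlation. Those not given above had at most adjusted p = 0.0495, and at least adjusted p = 0.079 with an estimated correlation. Higher were proliferation (6 and 6 of 20, 1 and 1 lower) and stress (7 and 8 of 14). Lower were osteoclast (7 and 9 of 12, 1 and 1 higher), cartilage (6 and 7 of 15, 2 and 2 higher), tendon (8 and 8 of 16), protease (9 and 10 of 19, 0 and 1 higher), Wnt (7 and 7 of 19, 1 and 1 higher), limb patterning (15 and 15 of 21), macrophage (8 and 9 of 13), endothelium (2 and 1 of 11) and pericyte (5 and 6 of 10). limma called 4365 genes, 1802 higher and 2563 lower.

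The lists of other cell types were not called between levels at 12 days: neutrophil (adjusted p = 0.0783), erythroid (0.609), adipocyte (0.831), skeletal muscle (0.374), endothelium (0.612), pericyte and smooth muscle (0.630), Schwann cell and nerve (0.831), sweat gland (0.993) and mitochondrial transcripts (0.181), nor were the hypoxia (0.181) and stress (0.561) lists. Median, mean and test differed in sign at 12 days for the osteocyte, epidermis, Wnt, adipocyte, pericyte, Schwann and sweat gland lists, none of them called. With 2 members measured each, the lymphocyte and melanocyte lists were not tested as sets: Ighm and Cd4 were not called between levels on any day, and Mitf was higher after distal amputation at 12 days (0.78, adjusted p = 0.0250) and at 21 days (0.76, adjusted p = 0.0344), while Pmel was not called on any day (-0.26, -0.21 and -0.21).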

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

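The tests of scaling, of epidermis share, of shared keratin reads and of the spread at 14 days were chosen only after the result was seen; the test of nail tissue amount and the splits of the libraries were not.

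Real and other splits of the same libraries were compared for every count. Of 35 splits, 1, the real one, reached its count in each of the 9 comparisons of 2 groups, which argues against chance assignment of libraries there. With 35 splits the lowest possible share is 1 in 35. The splits also treat the libraries as independent, which the labels do not show. The real values and the highest of the other splits were 3053 and 2, 811 and 1, and 2656 and 37 between levels at 12, 14 and 21 days. For the days after distal amputation they were 2915 and 10 (12 to 14), 5234 and 203 (14 to 21) and 3584 and 3 (12 to 21). After proximal amputation they were 2288 and 3, 4328 and 125, and 4365 and 99. For the difference between levels in the change, 100 splits were compared, the real one included. Only the real one reached 2234, with 107 as the highest other. The drawn splits shuffled libraries across days and levels together. They therefore also broke up the plain day and level differences and cannot decide on this difference alone.

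Proliferation genes were higher after distal amputation at 12 days and lower at 21 days, with a median difference between levels in the change of -1.11; none of these list calls held with an estimated correlation (adjusted p = 0.132, adjusted p = 0.268 and adjusted p = 0.0644). The list median was -1.09 under the scaling that brought it nearest to 0 and -1.20 with table totals, so the choice among these scalings did not make the difference. In this contrast the median of all genes was -0.012, 0.006 with median-ratio factors and -0.105 with table totals. Such small shifts could not have brought the list near 0, so the test does not decide on scaling in general. A different share of epidermis as a whole is argued against as the whole cause, since the epidermis list had a median of -0.17 with a median absolute deviation of 0.69. The list mixes genes of several epidermal layers, so a changed share of a single layer is not covered. A difference in cycling between the amputation levels may underlie it, a hypothesis drawn from these same libraries and not tested separately. Other mixtures of tissue were not tested. In the same contrast the nail (median -1.44), osteoclast (-0.83) and neutrophil (-4.22) lists also differed downward. The cartilage (1.51), tendon (1.08), fibrosis (1.08), limb patterning (0.98), Wnt (0.38) and BMP (0.38) lists differed upward. A changed mixture of these tissues therefore cannot be told apart from a difference in cycling. Of the direction along which a factor looks removed from the deposited values, 0.194% lay between groups. That argues against the removal of this direction as the whole cause. The direction with the next least spread also lay below sampling noise, and its share between groups was not computed. A factor removed along it is therefore not covered.

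Nail matrix and hard keratin genes were higher after distal amputation at 12 and 21 days, calls that ended with an estimated correlation (adjusted p = 0.0862 and adjusted p = 0.268). Reads shared between near-identical keratin genes cannot account for the members that are not keratins. Of these, 3 of 5 were higher at 12 days: Hoxc13, Foxn1 (1.24) and Dlx4 (1.02), but not Lgr6 (-0.16) or Tchh (0.06). At 21 days the same 3 were higher (0.65, 1.07 and 0.97), Lgr6 was not called (-0.19) and Tchh was lower (-1.91). These genes do not show whether each keratin gene differed on its own, which was not tested. A varying amount of nail tissue between libraries cannot be told apart from regulation: members deviated together within groups, with a median pairwise correlation of 0.341, against at most 0.126 in 200 random lists. That value lies between the bounds set for either answer. How much nail a library held may follow from the amputation level itself.

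Fewer genes were called between levels at 14 days than at 12 or 21 days. Whether a larger spread between libraries at 14 days contributed cannot be told from the test. The main fit gives each gene the same error on all 3 days, so extra spread could not raise the error at 14 days alone. For the same reason the SD within groups does not decide the counts. The median SD at 14 days was 1.06 times that of the other days. The SD was 0.183 in the proximal 14 day group, the highest of the 6, against 0.154 to 0.166 in the others. The lowest quality weight of all libraries, 0.516, was that of proximal 14 day replicate 3. In fits of the compared groups alone, where each day has its own error, the counts were 2659, 261 and 1917 at 12, 14 and 21 days. Those fits hold fewer libraries, and the part of spread in their counts was not tested. Fold changes were smaller, with an SD over genes of 0.313 at 14 days, 0.499 at 12 and 0.441 at 21. Whether these smaller fold changes reflect a smaller biological difference at 14 days was not tested separately.

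Libraries that lay far from the others of their group were found in 23 of 408 groups of 4 values, where chance gives about 1 in 20, or 20.4. For genes, values outside were Msx1 in distal 21 day replicate 4 (646, others 506 to 522), Krtap9-1 in proximal 14 day replicate 4 (1677, others 136 to 180), Krt42 (50140, others 31056 to 31497) and Krt90 (49260, others 29726 to 31987) in the same library, and Pamr1 in proximal 21 day replicate 4 (77, others 151 to 153). Aox4 was at 80 in distal 12 day replicate 2 (others 140 to 153) and at 49 in distal 14 day replicate 3 (others 30 to 32). Pck1 was at 97 in proximal 12 day replicate 1 (others 20 to 24), where Tnfrsf13c was at 50 (others 13 to 15). In distal 14 day replicate 4 Tnfrsf13c was at 11 (others 39 to 50) and Mmp12 at 11 (others 16 to 17). Mmp12 was at 20 in proximal 14 day replicate 2 (others 107 to 143), and Creg2 at 401 in distal 21 day replicate 1 (others 251 to 256).

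List scores far from their group were osteoblast -1.06 in distal 21 day replicate 3, osteocyte 0.31 in proximal 14 day replicate 1, osteoclast -0.23 and skeletal muscle -0.14 in distal 21 day replicate 4, proteases -0.017 in distal 14 day replicate 1, nail -0.16 in distal 12 day replicate 1, epidermis 0.56 in proximal 21 day replicate 1, BMP -0.29 in proximal 12 day replicate 2, pericyte and smooth muscle 0.79 in proximal 14 day replicate 3, and Schwann cell 0.76 in proximal 12 day replicate 3.

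The change from 12 to 21 days differed between levels, by the test of that difference, for 2234 genes. Named genes were Acan (2.61), Col10a1 (4.53), Col9a2 (2.96), Crnn (3.48), Cyp26a1 (3.10), Msx1 (1.15), Postn (1.42), Mki67 (-1.19), Krtap26-1 (-4.27), Mmp3 (-4.17), S100a8 (-5.13) and S100a9 (-6.28). List medians that differed were cartilage 1.51, tendon 1.08, fibrosis 1.08, limb patterning 0.98, Wnt 0.38, BMP 0.38, osteoclast -0.83, nail -1.44, proliferation -1.11 and neutrophil -4.22; with an estimated correlation none of these 10 lists was called (lowest adjusted p = 0.0635).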

How the results depend on the processing

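The pseudocounts of 0.5 and 8, the filter at a mean value of 50, the low-spread covariate and, for the list tests, quality weights, the filter of 1 per 1e+06, only the compared groups and leaving out libraries were chosen only after the result was seen; the other alternatives were fixed beforehand. The 2 count models of the design were not run because the deposited values are not raw counts, and depth is unknown.

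No named gene or list test reversed, but the larger direction of the called genes did. With median-ratio factors the counts higher and lower were 1605 and 1446 between levels at 12 days (main 1392 and 1661), 1579 and 1031 at 21 days (main 1237 and 1419) and 1211 and 1072 for 14 against 12 days after proximal amputation (main 1107 and 1181). With table totals they were 3015 and 1563 for 21 against 14 days after proximal amputation (main 1876 and 2452), and with only the compared groups 968 and 949 between levels at 21 days. Over the alternatives, 4708 values of named genes stayed on their side of the threshold, 150 lost a call and 43 gained it; for list tests these were 2620, 188 and 48. Of the list losses, 89 came with an estimated correlation: of 22 list calls between levels it kept 2, and fry kept 13 and gained 4. The count between levels at 14 days, 811, was 450 with table totals and 261 with only the compared groups; that at 21 days, 2656, was 4186 with table totals. The cause was not tested. Leaving out 1 library gave 277 to 950 genes at 14 days, with 302 without distal replicate 3 and 380, 397 and 322 without proximal replicates 1, 2 and 3; these fits hold fewer libraries by construction. It gave 2344 to 2732 at 12 days and 1827 to 2417 at 21 days. After distal amputation it gave 2213 to 2721 (12 to 14 days), 4449 to 4910 (14 to 21) and 2919 to 3208 (12 to 21), after proximal amputation 1649 to 2180, 3401 to 4197 and 3616 to 3992, and 1729 to 2178 for the difference between levels. With the low-spread covariate the counts between levels were 2814, 598 and 2363.

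Replicate numbers did not pair the libraries throughout: correlations of same-numbered libraries ran from -0.19 to 0.70, in 0 of 9 comparisons did every pair exceed 0.1, and 9 of 36 pairs correlated best with their own number. The 0.70 was between proximal 12 and 14 day replicate 3, and replicate 2 of these groups reached 0.28. Both pairs correlated best with their own number. What these libraries shared was not tested. With the number as a block, 3027, 700 and 2653 genes were called between levels at 12, 14 and 21 days, and 2208 for the difference between levels.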

Other observations

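The genes below were chosen after their values were seen, among those called on all 3 days and not by a fixed rule, so genes of similar size are left out. In fits of the compared groups alone, 51 genes in place of 135 were called on all 3 days. No test beyond the limma fit was run on them.

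Genes higher after distal amputation on every day included Pappa2, which encodes a protease of insulin-like growth factor binding proteins, by 3.09, 2.12 and 2.05 on the log2 scale at 12, 14 and 21 days, Mtcl1 by 1.68, 1.53 and 3.32, and Zic2, a zinc finger transcription factor gene, by 1.44, 1.55 and 2.75. Krt90 was higher by 3.83, 1.67 and 3.17. There were 26 genes lower at 12 days and higher at 14 and 21 days, and 5 with the opposite order. These 5 were Rrp1b (0.38, -0.25 and -0.27), Polr1b (0.38, -0.29 and -0.24), Heatr1 (0.46, -0.23 and -0.25), Mdn1 (0.31, -0.33 and -0.22) and Lrpprc (0.21, -0.20 and -0.25). Polr1b encodes a subunit of RNA polymerase I, and Heatr1 and Mdn1 act in ribosome production. The 2 genes higher at 12 and 14 days and lower at 21 days were Mad2l1 (0.47, 0.39 and -0.60), a spindle checkpoint gene, and Tmem97 (0.47, 0.53 and -0.34).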
